A study of Mus musculus with 8 samples.

How the data were processed

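The series holds 8 single-cell RNA libraries of mouse embryonic cerebellum from the FCG mouse line (core genotypes), in which the Sry transgene uncouples gonads from sex chromosomes. Each of the 8 combinations of stage (E16.5 or E18.5), chromosomes (XX or XY) and gonads (ovaries or testes) has 1 library. Per the labels' protocols, cerebellar structures were dissected, dissociated with papain and run on the Chromium Controller with the Single Cell 3' V3 and V3.1 chemistries; which library had which chemistry is not given in the sources used here. Per the submitters' processing notes, Cell Ranger 5.0.1 was used with the build mm10; the annotation and the rule that picked cell barcodes are not given there. The deposited matrices hold UMI counts as whole numbers per gene and barcode, with no normalization and with no barcode under 500 UMIs. They list 32285 genes by Ensembl identifier and symbol, and 78 of these share a symbol with another identifier. Positions were taken from GENCODE M21 (mm10), which holds 32235 of the identifiers.

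The rest was computed from these counts. Barcodes were kept with at least 500 genes detected and at most 10% of UMIs from mitochondrial genes. In each library doublets were simulated by summing pairs of cells, and the cells with the highest share of simulated neighbours were removed at 0.8% per 1000 barcodes. Counts were scaled to each cell's total and log-transformed, and 2000 variable genes were reduced to 40 principal components. Leiden clusters (resolution 1.5, 20 neighbours) were built on 3500 cells per library, and the other cells took the most frequent cluster of their neighbours. Genes on the Y, Xist, Tsix, mitochondrial, ribosomal and haemoglobin genes and a distal X interval were left out of the clustering. Clusters were named from fixed marker genes. A type was open to a cluster in which at least 3 of its markers were found in 10% of cells and stood 2-fold over the median cluster, with a mean marker level within 4-fold of the type's highest cluster. A cluster stayed unnamed where its top 10 genes held more markers of another type, or where it had few UMIs and no marker among those genes. Names end in "-like", since no other evidence of identity was at hand. Clusters without a name kept their number, and 3 unnamed clusters with few UMIs (10, 14 and 37) were pooled and left out of the fits within classes.

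Counts were summed per library, and per library and class, so that the library was the replicate and never the cell. Each gene was tested with the quasi-likelihood F test of edgeR 4.0.16 (TMM scaling, filterByExpr) in an additive model of stage, chromosomes and gonads over all 8 libraries, with 4 residual degrees of freedom. Each level of a factor thus had 4 libraries, and each contrast compared 4 pairs of libraries that differed, by their labels, in that factor alone. By gonads and by chromosomes, each pair set an XX ovaries or XY testes library against an XX testes or XY ovaries library. Interactions were tested by adding 1 term, with 3 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fits within classes used the 10 classes with at least 30 cells in every library. Log2 fold changes used a prior count of 2, and CPM values in the text are means over libraries with the SD. Class shares were tested with edgeR on cell numbers with the library's kept cells as offset, and with an exact two-sided permutation within pairs, whose smallest possible p is 0.125. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with the preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's members move, on balance, 1 way. A list with fewer than 3 measured members was not tested, which left 27 of the 28 lists. A maturation axis took, per library and class, the mean log2 CPM of the genes called higher at E18.5 minus that of the genes called lower, and compared gonads and chromosomes on it with the exact permutation within pairs.

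The cell filter, marker lists, gene lists, models, other settings to try and rule for named genes were fixed before the data were examined. The rule named, for each contrast, the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 10 CPM and the same direction in all 4 pairs. It took the 3 highest and 3 lowest in each class by the same rule, and list members that passed the test, of which 2 to 4 per list are given. Genes it always named included Xist, Ddx3y, Eif2s3y, Kdm5d, Uty, Sry, Esr1, Mki67, Fkbp5, Gli1, Atoh1, Foxj1, Gfap, Aqp4, Hes5, Tmsb4x and Gpm6b. Genes named outside it are said to be so. Within classes the text gives part of the genes the rule took.

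The other settings were RLE size factors, library totals only, no filter on low counts, DESeq2 1.42.0, counts thinned to equal totals, equal cell numbers, the factor without covariates, doublets kept, a stricter cell filter (1000 genes, 5% mitochondrial), resolutions of 0.75 and 3, neural cells as the denominator, the exact permutation, and leaving out each library in turn. Further settings, chosen after seeing the data, added the gonads by chromosomes term to each model and left non-neural classes out of the sums. The fits were tested on simulated data in which 200 genes were changed by folds of 1.5, 2 or 4 in counts drawn from the real libraries' means and totals. Changes of 4-fold were recovered for 100% of the genes in each contrast. The changed genes were drawn from those with a mean of at least 10 CPM. For whole libraries, 2-fold changes were given to 67 genes per contrast. Of these 46.3% were recovered by gonads (19454 genes tested), 59.7% by chromosomes (19453 genes tested) and 56.7% by stage (19451 genes tested). Changes of 1.5-fold were recovered for 5.97%, 5.97% and 11.9%. For shares, 1 class raised 3-fold was called, with 0 of the other classes. This was a single draw per contrast for GABAergic interneuron-like cells, with a preset spread between libraries that was not estimated from the real shares. The real fit by stage missed larger changes, in glutamatergic nuclear neuron-like and oligodendrocyte lineage-like cells.

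Shares of cells for a single library have exact Clopper-Pearson intervals at 95%, and a count of 0 was read as allowing up to 3 counts; both cover counting error only. For shares of cells with a UMI, cells were also thinned to 2000 UMIs. Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9) and R 4.3.3 were used. Raw reads were not used here.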

Results

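Single-cell RNA was measured in the embryonic cerebellum of the FCG mouse line, in which gonads and sex chromosomes vary independently. The 8 libraries covered E16.5 and E18.5, XX and XY chromosomes, and ovaries and testes, with 1 library per combination, so no combination was replicated and each level of a factor had 4 libraries. The libraries held 122866475 to 253134581 UMIs each, over 122124 barcodes in all. After the filters on genes and mitochondrial share 103781 barcodes remained, of which 13278 were removed as doublets, 729 to 3076 per library. There were 90503 kept cells, 8415 to 15124 per library. In the order XX ovaries, XX testes, XY ovaries and XY testes, the median UMIs per kept cell were 12161, 10241.5, 6417 and 11529.5 at E16.5, and 13246, 10487, 10370 and 13160 at E18.5.

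Cells fell into 18 classes. The largest named ones were granule progenitor-like (16703 cells), granule neuron-like (15913 cells), astroglia or radial glia-like (10824 cells), GABAergic interneuron-like (6038 cells) and Purkinje-like (5752 cells). Unnamed cluster 2 (5154 cells) was led by Tlx3, Thrsp and Insm2, and unnamed cluster 3 (5007 cells) by Mgarp, Barx2 and Neurod4. Low-UMI unnamed clusters, 10 and 14 led by haemoglobin genes and 37 by Cyp26b1 and Tnc, made up 3.03% to 16.3% of a library's cells, with the highest share in the E16.5 XY ovaries library. Some classes drew on different clusters in different groups. Cluster 18 held the most Purkinje-like cells at E16.5, with ovaries and with XX chromosomes, and cluster 19 at E18.5, with testes and with XY chromosomes. For granule neuron-like cells it was cluster 9 at E16.5, with testes and with XY chromosomes, and cluster 11 at E18.5, with ovaries and with XX chromosomes. In astroglia or radial glia-like cells cluster 26, led by Col2a1 with Htra1 and Tenm4 among its leading genes, held 255 to 298 cells per library at E16.5 and 24 to 110 at E18.5.

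Xist and Y-linked transcripts matched the chromosome label in 8 of 8 libraries. Xist, the RNA that coats the inactive X (ENSMUSG00000086503, X from 103460366 to 103483254 in mm10), stood at 1131, 1339, 1053 and 1325 CPM in the XX libraries and at 0.160 to 0.350 CPM in the XY libraries. The sum of Ddx3y, Eif2s3y, Kdm5d and Uty was 161, 167, 161 and 119 CPM in the XY libraries. In the XX libraries it was 0.0192, 1.14, 0.0208 and 0.0366 CPM, and the highest of these, in E16.5 XX testes, came from 133 UMIs. A Y-linked UMI was found in 50.1% to 78.3% of XY cells and in 0.0238% to 0.692% of XX cells; after thinning to 2000 UMIs per cell, which left out 462 to 4457 shallower cells per library, these shares were 20.9% to 28.0% and 0% to 0.242%. An Xist UMI was found in 80.5% to 91.3% of XX cells (80.1% to 86.6% thinned) and in 0.105% to 0.246% of XY cells. Sry gave 0 UMIs in every library, which allows up to 0.0166 to 0.0343 CPM, so the Sry transgene that sets the gonads was not detected and the gonad labels had no check of their own.

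**Figure D1:**
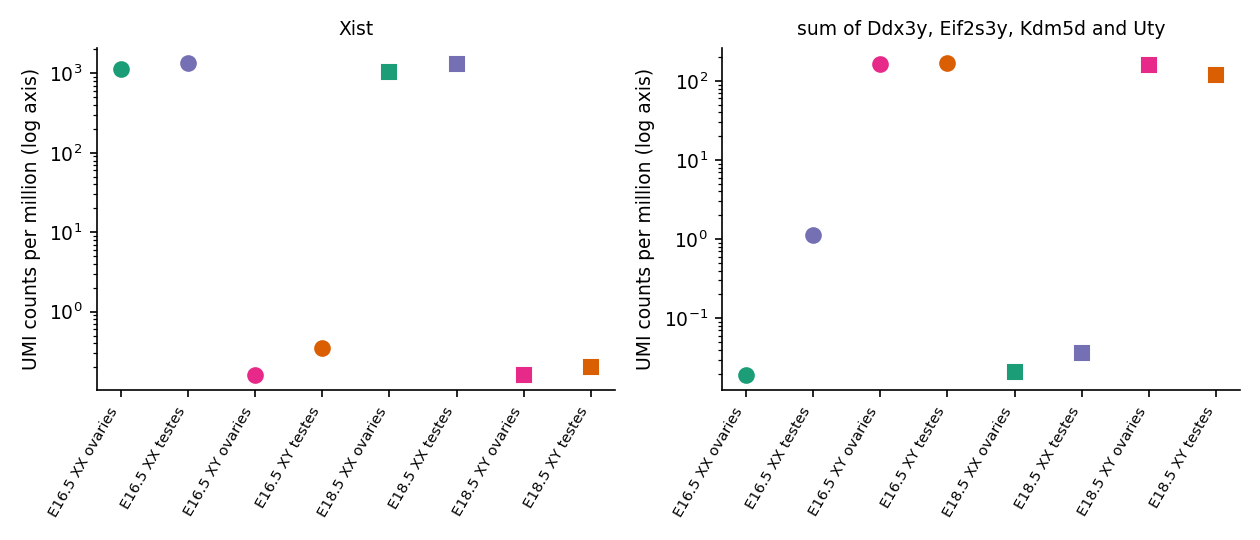
Xist and the sum of 4 Y-linked genes in each of the 8 libraries, in CPM on a log axis. The 4 XX libraries sit between 1053 and 1339 CPM for Xist and the 4 XY libraries between 119 and 167 CPM for the Y-linked genes.

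The comparison of testes with ovaries asked whether gonadal hormones change the embryonic cerebellum, including the targets of androgen. No gene differed in whole libraries (0 of 19713 called by edgeR, 22 at an unadjusted p under 0.05). DESeq2 called 2, Hccs and Tmsb4x, which both lie at the distal end of the X. Within the 10 classes edgeR called 0 of 128147 class and gene pairs (770 at an unadjusted p under 0.05), and DESeq2 called 0 as well. The counts of 0 stayed when the model held a gonads by chromosomes term, an alternative chosen after seeing the data. Without the E16.5 XX ovaries library 3 pairs were called, all lower with testes and all embryonic haemoglobin transcripts: Hbb-y in astroglia-like cells, and Hba-x and Hbb-y in GABAergic interneuron-like cells. None of the 18 classes differed in its share of cells (0 called by edgeR), including granule progenitor-like cells at 17.6% ± 3.83 (SD, n = 4) with ovaries and 19.4% ± 3.37 with testes. On simulated data of this design, changes were given only to genes with a mean of at least 10 CPM. Of the genes so changed, whole libraries recovered 5.97% at 1.5-fold, 46.3% at 2-fold and 100% at 4-fold. Granule progenitor-like cells, the largest class, recovered 44.8% at 1.5-fold and 100% at 2-fold. GABAergic or neurogenic progenitor-like cells recovered 22.4% at 1.5-fold and 86.6% at 2-fold, and the other classes were not simulated. The real fit of whole libraries missed changes larger than these by chromosomes, in Ddx3y, Eif2s3y, Kdm5d and Uty.

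The androgen response list showed no shift with testes. Of its 90 measured members 37 had a positive log2 fold change, with a median of −0.02 that turned to 0.01 under scaling by library totals (camera adjusted p = 0.391, and 0.826 with an estimated correlation). None of its members was called, over all genes or adjusted over the list alone, in whole libraries or in any of the 10 classes. Fkbp5, a target of steroid hormone receptors, stood at 30.5 CPM with ovaries and 31.0 with testes (log2 0.02 ± 0.11 SE, adjusted p = 1). The oestrogen receptor Esr1 stood at 1.78 and 1.88 CPM (log2 0.06 ± 0.25). Proliferation and glial genes were not called either: Mki67 (log2 −0.08 ± 0.24), Gli1 (0.14 ± 0.26), Atoh1 (0.09 ± 0.13), Hes5 (0.10 ± 0.59), Gfap (−0.08), Aqp4 (−0.10 ± 0.17), Foxj1 (−0.68 ± 1.29) and Gpm6b (0.09 ± 0.23), each with an adjusted p of 1. Tmsb4x, an actin-binding peptide, averaged 6266 ± 1108 CPM with ovaries and 4644 ± 679 with testes (log2 −0.43 ± 0.12, adjusted p = 1), lower with testes in 4 of 4 pairs.

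Of the 27 lists tested, camera called 6 for testes against ovaries, and none held with an estimated correlation. The S phase list (22 of 28 members positive, median 0.05, adjusted p = 0.826 with an estimated correlation) and the granule lineage list (12 of 13, median 0.07, 0.642) lay higher. The astrocyte maturation list (3 of 20 positive, median −0.16, 0.826) and the hypoxia and glycolysis list (2 of 20, median −0.12, 0.642) lay lower. Beside them, lists of other cell types, not called, also had few positive members: choroid plexus (0 of 10, median −0.77), ependymal and motile cilia (1 of 15, −0.46), microglia and macrophages (1 of 12, −0.32) and vascular (1 of 12, −0.25). The Y-linked list lay higher (4 of 4, 0.642), beside the 1.14 CPM of the E16.5 XX testes library. The distal X interval lay lower (6 of 15 positive, median −0.43, 0.642), and Hccs, a haem lyase of mitochondria, was its 1 member called when adjusted over the list alone (−0.51 ± 0.09). Within classes 43 of 252 class and list pairs were called and 0 with an estimated correlation. Among them the dissociation and immediate early list had 3 members called higher and the distal X interval 8 lower, both adjusted over the list alone. Haemoglobin made up 0.0878% to 1.35% of the kept UMIs of a library.

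The comparison of XY with XX asked what the sex chromosomes change apart from the gonads. In whole libraries Xist alone was called, at 1194 ± 66.6 CPM in XX and 0.222 ± 0.0993 in XY (log2 −12.42 ± 0.33, adjusted p = 2.78e-04, 4 of 4 pairs). Genes at an unadjusted p under 0.05 numbered 53, and DESeq2 called 10, among them Tsix, Ddx3y, Eif2s3y, Kdm5d, Uty and Eif2s3x. The Y-linked genes averaged under 0.1 CPM in XX, and in XY 61.2 ± 14.9 for Ddx3y, 43.5 ± 15.1 for Eif2s3y, 25.2 ± 2.97 for Kdm5d and 23.5 ± 4.01 for Uty, yet missed the threshold over all genes (adjusted p = 0.957, 0.257, 0.834 and 0.0622); adjusted over the list alone 4 of 4 were called. Their XX values near 0 include the E16.5 XX testes library, without which edgeR called 4 genes (Eif2s3y, Kdm5d, Uty and Xist); without the E18.5 XY ovaries library it called 3 (Tsix, Uty and Xist). Within classes 58 pairs were called: Ddx3y, Eif2s3y, Kdm5d and Uty higher and Xist and Tsix lower in 9 of the classes, and 4 of these 6 genes in erythroid-like cells. In astroglia-like cells Ddx3y stood at 62.1 CPM in XY libraries, and in Purkinje-like cells at 42.9 ± 2.17. The pooled XY means cover groups that differed in the ratio of Ddx3y to Eif2s3y CPM. In whole libraries this ratio was 1.60 at E16.5 and 2.80 at E18.5 in XY ovaries, and 0.909 and 1.05 in XY testes. Within each stage it was higher in XY ovaries in every class fitted. The ratio was not among the planned comparisons, and its cause was not tested.

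Genes known to escape X inactivation were lower in XY, and this list held with an estimated correlation (adjusted p = 0.00682) as did the Y-linked list (0.0209). All 8 measured members had a negative log2 fold change, with a median of −0.49; 0 were called over all genes and 7 adjusted over the list alone, among them Eif2s3x (−0.57 ± 0.08), a translation initiation factor, and the histone demethylases Kdm6a (−0.64 ± 0.15) and Kdm5c (−0.44 ± 0.11). In the 10 classes, camera called the list lower in 10, 3 of them with an estimated correlation, and 46 class and gene pairs were called lower adjusted over the list alone. Camera called 5 more lists that did not hold with an estimated correlation. The S phase and G2M lists lay lower, with 0 of 28 members positive in each and medians of −0.18 and −0.18 (adjusted p = 0.226 for both with an estimated correlation). The granule lineage list lay lower (3 of 13 positive, median −0.06, 0.497), beside granule progenitor-like shares of 20.4% ± 2.48 in XX and 16.5% ± 3.47 in XY. The oxidative phosphorylation list lay higher (23 of 25 positive, median 0.18, 0.580), as did the distal X interval (9 of 15, median 0.37, 0.226), in which Hccs was called adjusted over the list alone (0.51 ± 0.09). Beside them, lists of other cell types, not called, also had mostly positive members: microglia and macrophages (12 of 12, median 0.47), choroid plexus (9 of 10, 0.48), haemoglobin (8 of 10, 0.47) and ependymal and motile cilia (14 of 15, 0.55). Over the classes 69 of 252 class and list pairs were called, and 12 with an estimated correlation. The androgen response list did not shift (49 of 90 positive, median 0.01 that turns to −0.01 under RLE scaling, mean 0.10 and camera downward, adjusted p = 0.922).

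No class share differed by chromosomes (0 of 18 called by edgeR). Granule progenitor-like cells were a smaller share in XY in 4 of 4 pairs (log2 −0.32 ± 0.11, adjusted p = 0.483, exact permutation p = 0.125, the smallest this design allows), and unipolar brush cell-like cells also in 4 of 4 pairs (6.28% ± 2.30 against 5.03% ± 1.90, adjusted p = 1). Mki67 had a log2 fold change of −0.21 ± 0.24 and Tmsb4x of 0.37 ± 0.12 (4745 CPM in XX and 6165 in XY), with an adjusted p of 1 for each. A maturation axis placed each library on the change from E16.5 to E18.5 within a class. With testes the libraries lay later in 4 of 4 pairs in granule progenitor-like cells, by 0.242 ± 0.146 (SD, n = 4 pairs) or 10.1% of the stage difference. The same held in granule neuron-like cells (0.116 ± 0.0655, 5.002%) and in GABAergic or neurogenic progenitor-like cells (0.351 ± 0.301, 11.7%). The exact permutation p was 0.125 in each, the smallest possible; none of the 9 classes had 4 of 4 pairs on 1 side for chromosomes, and with the 100 highest and 100 lowest genes in place of the called ones no class had 4 of 4 for either factor. The share of the stage difference moved with single libraries. In granule progenitor-like cells it was 6.04% without E16.5 XY ovaries and 5.30% without E16.5 XY testes. In granule neuron-like cells it was 8.24% without E16.5 XX ovaries, 0.448% without E16.5 XY ovaries, −4.11% without E16.5 XY testes, 9.69% without E18.5 XX testes, 0.319% without E18.5 XY ovaries and 8.88% without E18.5 XY testes. In GABAergic or neurogenic progenitor-like cells it was 25.5% without E16.5 XX ovaries, 3.33% without E16.5 XY ovaries and 4.41% (3 of 4 pairs) with doublets kept.

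The comparison of E18.5 with E16.5 asked what changes between these stages of the cerebellum. A library batch that parts the stages cannot be told from stage here, since the chemistry of each library is not given. Class shares are shares of kept cells, and a difference between the stages in which cells were recovered was not tested. Granule neuron-like cells rose from 13.1% ± 3.06 (SD, n = 4) to 22.3% ± 2.49 of cells (log2 0.77 ± 0.18 SE, adjusted p = 0.0419), and Purkinje-like cells fell from 11.9% ± 6.77 to 1.40% ± 0.436 (−3.12 ± 0.54, adjusted p = 0.0203), both in 4 of 4 pairs. The exact permutation p was 0.125 for each, the smallest this design allows. Classes past neither test but with 4 of 4 pairs on 1 side were unipolar brush cell-like (3.96% to 7.34%, adjusted p = 0.0626), oligodendrocyte lineage-like (0.0721% to 0.355%, 0.0626), granule progenitor-like (16.3% to 20.6%, 0.0685), glutamatergic nuclear neuron-like (1.87% to 0.0972%, 0.0837) and GABAergic interneuron-like cells (8.81% to 4.93%, 0.122). At E16.5 Purkinje-like shares were 14.6% in XX ovaries and 20.3% in XY testes, but 6.74% in XX testes and 6.07% in XY ovaries. At E18.5 they were 0.986% to 1.94%. Granule neuron-like shares were 9.04% to 16.3% in the E16.5 and 18.8% to 24.4% in the E18.5 libraries. With 1 library fewer, and so 3 residual degrees of freedom, calls were lost: without E16.5 XX ovaries or any 1 of the E18.5 libraries (XX ovaries, XX testes, XY ovaries, XY testes) 0 classes were called, without E16.5 XX testes 1 (Purkinje-like), and without E16.5 XY ovaries 3.

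**Figure D2:**
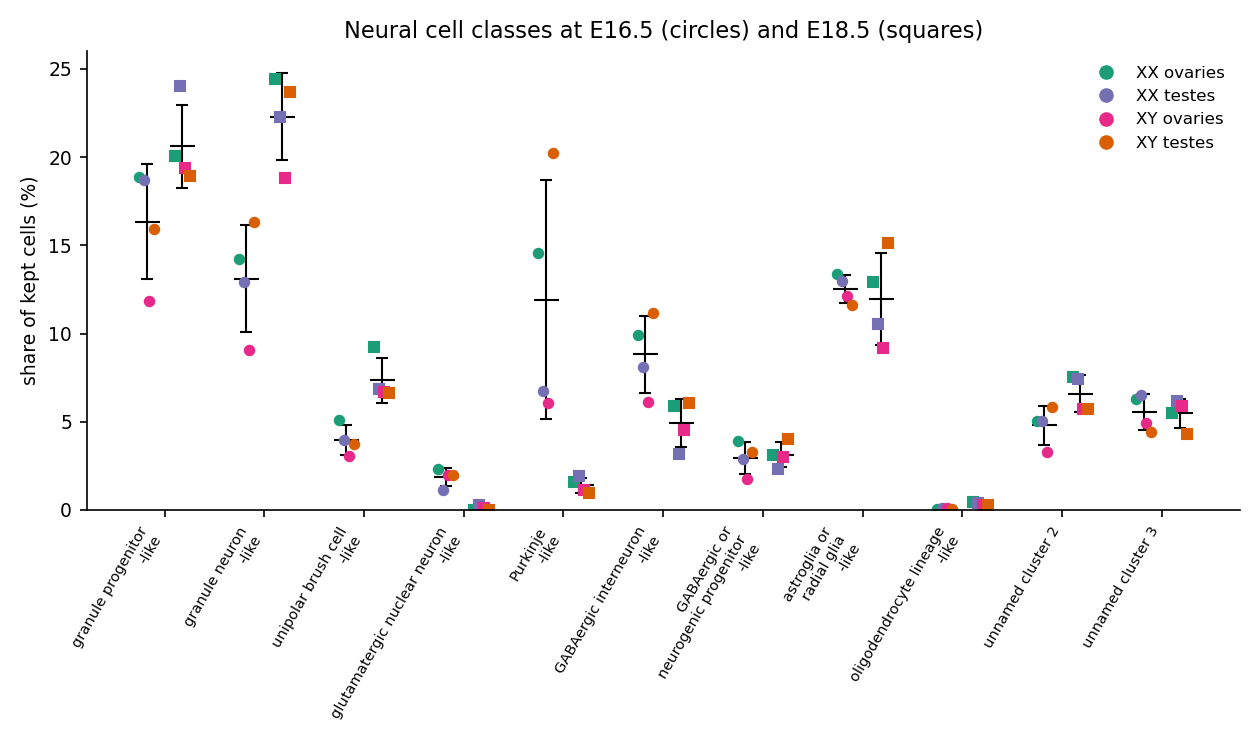
Share of kept cells (percent) of the neural classes in each library; points are libraries (circles E16.5, squares E18.5) and bars the mean and SD of the 4 libraries of a stage. Granule neuron-like cells go from 13.1% to 22.3% and Purkinje-like cells from 11.9% to 1.40%.

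In whole libraries 6 genes were called by stage. Tac2, which encodes neurokinin B (ENSMUSG00000025400, chromosome 10 from 127724478 to 127731768), rose from 0.831 ± 0.202 to 20.1 ± 5.54 CPM (log2 4.59 ± 0.19, adjusted p = 0.00515). Tbata rose from 3.06 to 19.2 CPM (2.68 ± 0.19), Rassf3 from 14.6 to 33.4 CPM (1.19 ± 0.09), and Thsd7a fell from 67.0 to 27.5 CPM (−1.29 ± 0.09), each with an adjusted p of 0.0380. Saa1 and 4631405J19Rik also rose, below the level set for named genes. Genes at an unadjusted p under 0.05 numbered 2901, and DESeq2 called 1636. The count was 2183 (942 higher and 1241 lower, all 6 genes among them) when the model held a gonads by chromosomes term, and 280 under scaling by library totals, which moved the median of all genes from 0.04 to −0.08. Without E16.5 XX ovaries, E16.5 XY testes, E18.5 XX ovaries, E18.5 XX testes or E18.5 XY testes 0 genes were called, without E16.5 XY ovaries or E18.5 XY ovaries 1, Tac2, and without E16.5 XX testes 7, of which Tac2 alone was among the 6. The glial genes Gfap (0.335 ± 0.0809 to 3.01 ± 0.358 CPM, log2 3.16 ± 0.28) and Aqp4 (3.37 to 10.3 CPM, 1.62 ± 0.17) had an adjusted p of 0.0570 each. The Sonic hedgehog effector Gli1 was at 1.28 ± 0.26 (adjusted p = 0.101), Hes5 at −1.11 ± 0.54 (0.431), Mki67 at 0.18, Atoh1 at −0.05, Foxj1 at 0.48 ± 1.04, Gpm6b at 0.31 and Tmsb4x at 0.13. Esr1 was at 1.89 and 1.76 CPM, and Fkbp5 at 31.7 and 29.8.

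Within classes 1856 class and gene pairs were called by stage, over 1282 genes, of which 913 were called in 1 class. Unipolar brush cell-like cells (59 higher, 68 lower) held the largest changes: Tac2 rose from 9.35 ± 2.16 to 330.4 ± 67.1 CPM (log2 5.14 ± 0.18, adjusted p = 2.01e-06), Grp, gastrin-releasing peptide, from 2.51 to 66.1 CPM (4.69 ± 0.39), and Myo1a by 3.67 ± 0.22, while the neuropeptide gene Tac1 (−3.30 ± 0.27), Vstm2l (−3.75 ± 0.49) and Meis2 (−2.91 ± 0.36) fell. In Purkinje-like cells (150 higher, 38 lower) Itpka rose from 1.95 to 35.1 CPM (4.09 ± 0.30), Itpr1, the calcium channel of the endoplasmic reticulum, from 25.8 to 197.0 CPM (2.93 ± 0.31) and Nexn by 2.84 ± 0.23. There the Purkinje markers Calb1 (1.36 ± 0.14), Car8 (1.30 ± 0.24) and Pcp4 (1.01 ± 0.19) rose, and Rorb (−2.04 ± 0.37), Cdh7 (−2.02 ± 0.35) and Cdh10 (−1.90 ± 0.17) fell. In astroglia or radial glia-like cells (259 higher, 139 lower) Lhfpl3 rose from 6.03 to 57.9 CPM (3.27 ± 0.17, adjusted p = 4.22e-04), with Nkx2-2 (3.09 ± 0.30) and Npy (2.42 ± 0.21). Lhfpl3 and Nkx2-2 belong to the oligodendrocyte lineage list, beside oligodendrocyte lineage-like shares of 0.0721% at E16.5 and 0.355% at E18.5. The water channel Aqp4 (2.01 ± 0.13), Apoe (1.67 ± 0.22) and the metallothionein Mt1 (1.65 ± 0.14) rose too, and Atoh1 (−2.52 ± 0.33), Msx3 (−2.38 ± 0.16) and Htra1 (−2.23 ± 0.30) fell, beside the fewer cells of cluster 26.

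Granule progenitor-like cells (153 higher, 222 lower) gained Tbata, from 7.28 to 43.1 CPM (2.60 ± 0.20), Pdgfra, from 8.16 to 38.3 CPM (2.23 ± 0.10), and Hpca (2.07 ± 0.15), and of the Sonic hedgehog pathway Gli1 (1.49 ± 0.19). The calcium buffer Pvalb fell there from 178.5 to 46.2 CPM (−1.95 ± 0.14), with Adgra1 (−1.94 ± 0.13) and Slc35f1 (−1.73 ± 0.17). In granule neuron-like cells (73 higher, 126 lower) Opcml (1.76 ± 0.21), Gm28050 (1.69 ± 0.17) and Tbata (1.67 ± 0.18) rose, and Meis2 (−1.96 ± 0.25), Adgra1 (−1.91 ± 0.16) and Gxylt2 (−1.41 ± 0.20) fell. In GABAergic interneuron-like cells (88 higher, 82 lower) Adamts18 rose from 4.80 to 32.3 CPM (2.77 ± 0.19) and the guidance cue Ntn1 by 1.92 ± 0.19, and Cartpt (−1.81 ± 0.20), Uncx (−1.70 ± 0.17) and Gad2, a GABA-synthesising enzyme (−0.79 ± 0.12), fell. GABAergic or neurogenic progenitor-like cells (19 higher, 15 lower) gained Hist1h3c (2.85 ± 0.44) and Adamts19 (2.20 ± 0.24) and lost Tenm4 (−2.44 ± 0.35) and Dhrs3 (−1.55 ± 0.17). Unnamed cluster 2 (92 higher, 89 lower) gained Tbata (2.52 ± 0.29), Pdgfra (2.38 ± 0.14) and C1ql1 (2.32 ± 0.19), and unnamed cluster 3 (85 higher, 99 lower) gained Shisa8 (2.96 ± 0.31) and lost Tac1 (−3.44 ± 0.20), Cartpt (−3.19 ± 0.31) and Pvalb (−3.05 ± 0.27). Erythroid-like cells had 0 genes called by edgeR, with 55 at an unadjusted p under 0.05. By DESeq2 the sum over classes was 4232. Without single libraries it was 925 (E16.5 XX ovaries), 365 (E16.5 XX testes), 478 (E16.5 XY ovaries), 782 (E16.5 XY testes), 773 (E18.5 XX ovaries), 863 (E18.5 XX testes) and 1107 (E18.5 XY testes), and with the gonads by chromosomes term it was 11868, which held all 1856 in the same direction.

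**Figure D3:**
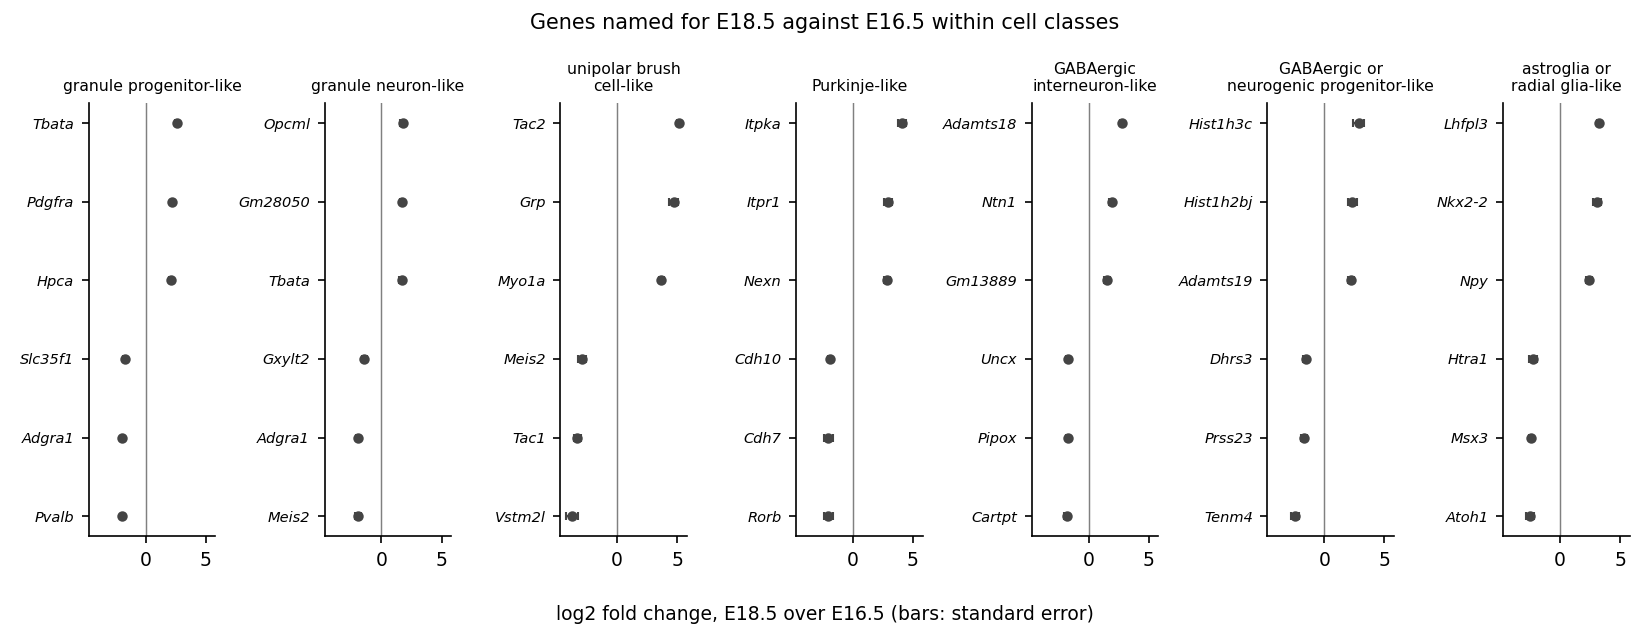
Log2 fold changes, E18.5 over E16.5, of the 3 highest and 3 lowest genes named in each of 7 classes; points are estimates over 8 libraries and bars the standard error. In unipolar brush cell-like cells Tac2 is at 5.14, and in granule progenitor-like cells Pvalb at −1.95.

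Camera called 16 of 27 lists by stage in whole libraries, and none of them held with an estimated correlation. The oxidative phosphorylation list lay higher (24 of 25 members positive, median 0.44, adjusted p = 2.64e-08, and 0.408 with an estimated correlation). Over all genes 0 members were called and 15 adjusted over the list alone, among them Uqcr11 (0.70 ± 0.15) and Ndufa2 (0.67 ± 0.12). Within classes it lay higher in 9 of 10, with 152 class and gene pairs adjusted over the list alone, and none of the 9 class calls held with an estimated correlation (lowest adjusted p = 0.315). Cell cycle lists lay higher, with 28 of 28 positive for G2M (26 under library totals, median 0.31, 0.386 with an estimated correlation) and 28 of 28 for S phase (24 under library totals, median 0.23, 0.410). The Purkinje lineage list lay lower (1 of 13 positive, median −1.31, 0.386), with 6 members lower adjusted over the list alone, such as Foxp2 (−2.35 ± 0.37) and Ebf2 (−2.32 ± 0.30), beside the smaller share of Purkinje-like cells. The granule lineage list lay higher (12 of 13, median 0.35, 0.287), with 5 higher adjusted over the list alone, such as Mfap4 (0.87 ± 0.17) and Neurod1 (0.86 ± 0.20), beside the larger share of granule neuron-like cells. The GABAergic interneuron lineage list lay lower (3 of 10 positive, median −0.74, 0.476) with 1 member, Gad2 (−2.03 ± 0.27), adjusted over the list alone, and the neuronal differentiation list also (3 of 20, median −0.21, 0.627).

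Glial and pathway lists lay higher at E18.5. They were astrocyte maturation (19 of 20 positive, median 0.54, adjusted p = 0.378 with an estimated correlation; 4 adjusted over the list alone, among them Gfap, Aqp4 and Mt3 at 1.12 ± 0.29), oligodendrocyte lineage (9 of 11, median 0.81, 0.287; 3 adjusted over the list alone, among them Nkx2-2) and Sonic hedgehog pathway (12 of 15, median 0.41, 0.386; 4 adjusted over the list alone, among them Ccnd1 at 0.68 ± 0.12). The hypoxia and glycolysis list (18 of 20, median 0.37, 0.378) had Ldha higher and the kinase Pfkp lower (−1.07 ± 0.12) adjusted over the list alone. The androgen response list lay higher (67 of 90 positive and 49 under library totals, median 0.13 and 0.01, camera adjusted p = 0.00828, and 0.287 with an estimated correlation), with 4 members adjusted over the list alone, among them Cdk6 (0.82 ± 0.09) and Ccnd1. The immediate early list, a sign of dissociation (21 of 22, median 0.47, 0.410), and the vascular list (12 of 12, median 0.68, 0.378) lay higher beside endothelial-like shares of 0.255% at E16.5 and 0.552% at E18.5. The haemoglobin list lay lower (0 of 10 positive, median −1.62, 0.627) beside erythroid-like shares of 5.85% at E16.5 and 2.45% at E18.5. These shares fell in XX testes (4.74% to 2.93%) and in XY ovaries (16.5% to 3.03%), the library that raised the E16.5 mean. They rose in XX ovaries (0.97% to 1.06%) and XY testes (1.15% to 2.77%). The distal X interval lay higher (13 of 15, 10 under library totals, median 0.18, 0.378). Fry called 2 lists by stage, oligodendrocyte lineage (adjusted p = 0.0385) and Polycomb repressive complex 2 (0.0385), the second not called by camera (0.297). Within classes 57 of 252 class and list pairs were called and 0 with an estimated correlation.

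The remaining lists were not called in any contrast for whole libraries. By stage their camera adjusted p was 0.0596 for sex steroid receptors and enzymes, in which the progesterone receptor Pgr was lower adjusted over the list alone (−1.73 ± 0.28), 0.171 for ependymal and motile cilia (14 of 15 positive), 0.518 for Notch and Wnt targets (9 of 16 positive, 7 under library totals), 0.642 for neural stem cell and radial glia (median 0.02, and −0.11 under library totals), in which Hopx was higher adjusted over the list alone (1.38 ± 0.19), 0.518 for choroid plexus, 0.769 for meninges and fibroblasts, 0.63 for microglia and macrophages (median −0.10, camera upward) and 0.657 for midbrain, brainstem and other regions. By gonads and by chromosomes these 8 lists and Polycomb repressive complex 2 had camera adjusted p values of at least 0.186 and 0.140 respectively. For some lists not called, median, mean and camera differed in sign. With testes these were sex steroid receptors (median −0.03, mean 0.02, camera upward), oligodendrocyte lineage (−0.05, −0.02, upward), haemoglobin (−0.17, −0.26, upward) and meninges (−0.10, 0.02, downward). In XY these were neural stem cell (0.03, 0.03, downward), oligodendrocyte lineage (0.01, 0.04, downward), Purkinje lineage (0.01, −5e-04, downward), Notch and Wnt (−0.01, 0.01, downward) and vascular (0.06, 0.08, downward). The X inactivation centre list, with Xist and Tsix, has 2 members and was not tested.

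Interactions asked whether an effect depended on another factor. Gonads by stage gave 0 genes by edgeR (21 at an unadjusted p under 0.05; DESeq2 6) and chromosomes by stage 0 (20; DESeq2 0), and within classes both gave 0 (442 and 556 at an unadjusted p under 0.05). Gonads by chromosomes gave 6820 genes of 19713 in whole libraries, 3417 higher and 3403 lower in the XX ovaries and XY testes libraries than in the XX testes and XY ovaries libraries, here called the concordant and the discordant libraries. Within classes it gave 31543 class and gene pairs, from 114 in erythroid-like to 5229 in granule progenitor-like cells. At least 9 of the 10 classes shared 616 of these genes, 416 higher in each, 200 lower in each and 0 mixed. Genes shared in this way, singled out after their values were seen, included the neuronal tubulin Tubb3 (1217 ± 62.7 CPM in concordant and 546 ± 114 in discordant libraries), the detoxifying enzyme Gstp1 (47.0 ± 21.7 and 8.02 ± 4.72) and Eno1 (349 ± 127 and 128 ± 25.1). Lower ones were Ttr, which choroid plexus cells secrete (7.31 ± 4.998 and 14549 ± 22663, with 48508 CPM in E18.5 XY ovaries and 2341 to 4670 in the other discordant libraries), AY036118 (39.8 ± 12.1 and 267 ± 184) and Hist1h4d (37.1 ± 11.01 and 110 ± 37.3). Without single libraries the whole-library count was 3306 (E16.5 XX ovaries), 3490 (E16.5 XX testes), 1702 (E18.5 XX ovaries), 4303 (E18.5 XX testes) and 4275 (E18.5 XY testes).

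The concordant and discordant libraries also differed in their cells. Meningeal fibroblast-like cells made up 0.0276% ± 0.0261 (SD, n = 4) of concordant and 4.58% ± 1.17 of discordant libraries (12 and 2397 cells), and choroid plexus-like cells 0.00590% ± 0.00680 and 1.78% ± 2.63 (2 and 1032 cells). Of these 1032 cells 866 came from E18.5 XY ovaries (5.73%), and the other discordant libraries had 0.396% to 0.508%. Microglia or macrophage-like cells made up 0.632% ± 0.312 and 2.10% ± 0.404, with most in cluster 31 in concordant and in cluster 33, led by Pf4 and Mrc1, in discordant libraries. Erythroid-like cells made up 1.49% ± 0.858 and 6.81% ± 6.54, with 16.5% in E16.5 XY ovaries and 2.93% to 4.74% in the other discordant libraries. GABAergic or neurogenic progenitor-like cells made up 3.597% ± 0.444 and 2.48% ± 0.571. The shares of these 5 classes did not overlap between the groups, and the exact permutation p of 0.0286 for such a split is the smallest that 4 against 4 allows (adjusted p = 0.103 over 18 classes). Median UMIs per cell were 11529.5 to 13246 in the concordant and 6417 to 10487 in the discordant libraries.

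**Figure D4:**
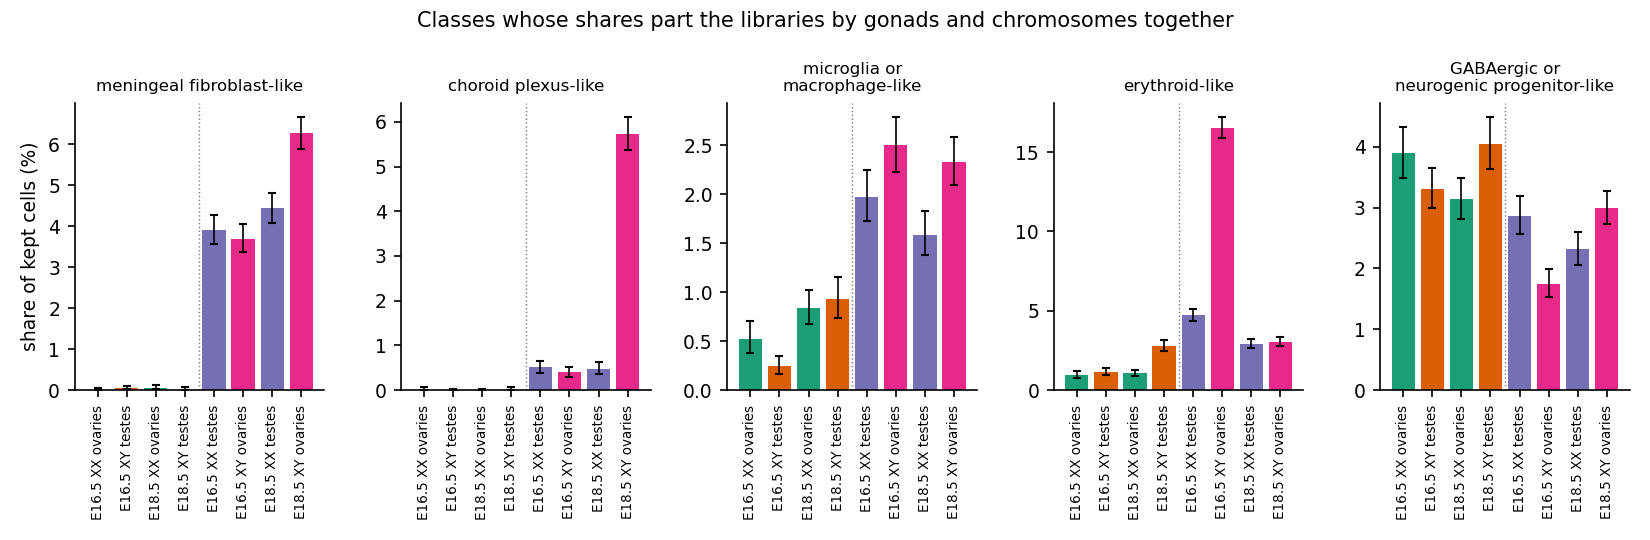
Share of kept cells (percent) of 5 classes in the concordant (XX ovaries, XY testes, left of the dotted line) and discordant (XX testes, XY ovaries, right) libraries; each bar is 1 library, with its exact Clopper-Pearson interval at 95%, which covers counting error only. Meningeal fibroblast-like cells average 0.0276% in concordant and 4.58% in discordant libraries.

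At the distal end of the X, Tmsb4x (ENSMUSG00000049775), Prps2, Msl3 and Hccs, the genes of this stretch with a mean of at least 10 CPM (X from 167207093 to 169320372 in mm10), lay higher in XY ovaries than in XX testes libraries at both stages. Their median log2 difference was 1.004 in whole libraries (0.79 to 1.93), and class medians ran from 0.784 to 1.49. Class medians cover the genes of the stretch with a mean of at least 10 CPM in that class. In GABAergic interneuron-like and Purkinje-like cells these were 3 genes without Prps2. In granule neuron-like and unipolar brush cell-like cells they were 4, with another gene in place of Prps2. Granule neuron-like cells gave the 0.99 and unipolar brush cell-like cells the 1.07 below. Against XX ovaries the median in XY ovaries was 0.92 (0.44 for Tmsb4x to 2.81 for Prps2, class medians 0.59 to 0.99), and against XY testes 0.897 (0.50 to 2.99, class medians 0.566 to 1.07). In XY testes against XX ovaries the same genes had a median of −0.03. Hccs stood at 38.4 and 41.5 CPM in the XY ovaries libraries (E16.5 and E18.5) and at 19.2 to 28.2 CPM in the other 6. Tmsb4x stood at 7129 and 7293 CPM and at 3999 to 5578 CPM. The neighbouring genes from Gemin8 to Egfl6 had a median of −0.06 and the other 321 genes of the X one of 0.01. Of 318 windows of 7 genes without these 4 genes, 0 reached the 0.791 of the window that holds them, and the highest was 0.396. The list from Gemin8 to Hccs was fixed beforehand; its part from Tmsb4x to Hccs, the windows and the comparisons of XY ovaries with the other groups were chosen after the values were seen.

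**Figure D5:**
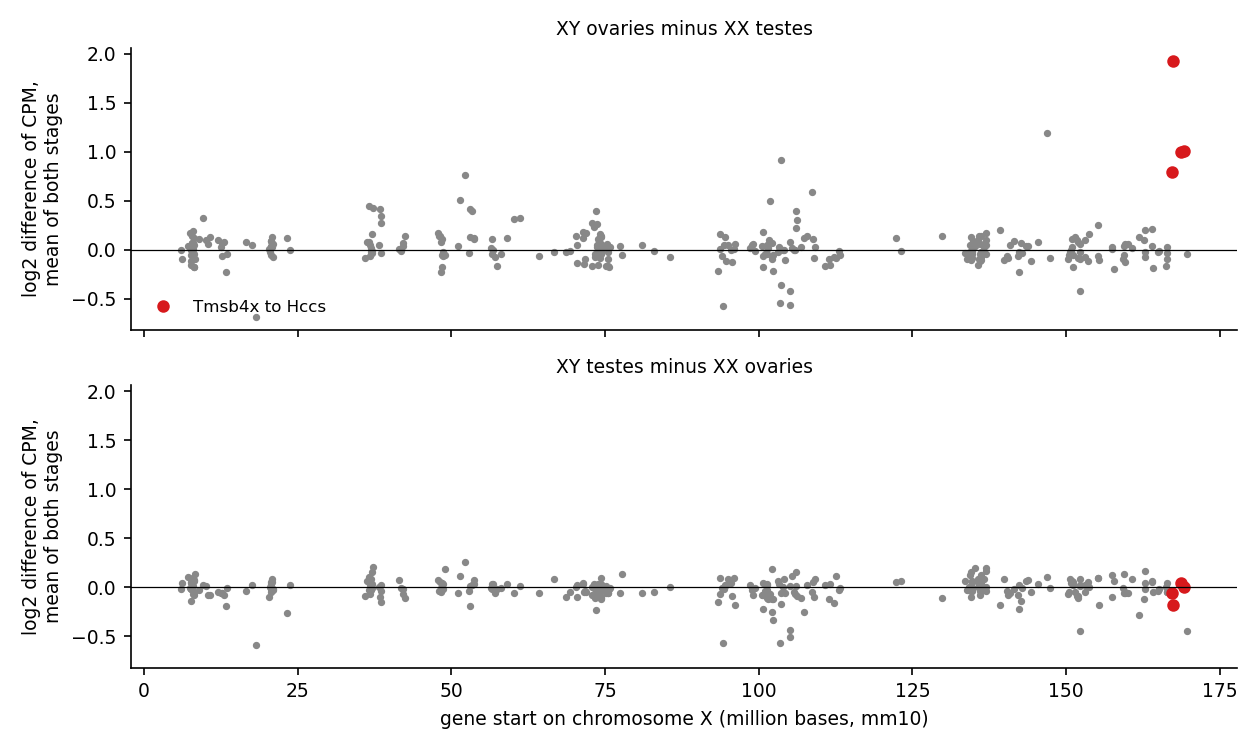
Log2 difference of CPM along the X (gene start in megabases, mm10), averaged over both stages, for XY ovaries minus XX testes and for XY testes minus XX ovaries; each point is a gene, without Xist and Tsix. The 4 genes from Tmsb4x to Hccs have a median of 1.004 in the first comparison and −0.03 in the second.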

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

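All tests of explanations in this part were chosen only after the results were seen, and so was the count of other splits for the interaction.

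The gonads by chromosomes interaction stood out because the effect of testes differed between XX and XY for 6820 genes in whole libraries and 31543 class and gene pairs. Of 32 splits of the 8 libraries 1, the real one, gave as many genes, and the highest other gave 0. The other splits keep this difference in their residual spread, and the count was made after the result was seen. It therefore does not exclude chance. Cells counted in the classes of meninges, choroid plexus and blood are not the whole source, since 6522 genes were called when these classes were left out of the sums. Leaving them out does not remove their free RNA from the neural cells, and Ttr was called in 10 classes. Free RNA was not tested for and stays open. A library batch that parts the concordant from the discordant libraries stays open: the difference was alike in every pair of classes, with a lowest correlation across genes of 0.628 (genes are not independent replicates), and the discordant libraries held more meningeal cells and fewer UMIs per cell. An effect of the gonads that depends on the chromosomes stays open too, since the difference correlated at 0.750 between the stages, which a batch that parts the libraries in the same way would also give, so these cannot be told apart with 1 library per combination.

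The genes from Tmsb4x to Hccs were higher in the XY ovaries libraries at both stages, by a median log2 of 1.004 against XX testes, 0.92 against XX ovaries and 0.897 against XY testes. A batch that raised these genes together in the discordant libraries would raise them in XX testes as well, but the highest class median of XX testes over XX ovaries was 0.124. Single genes moved in opposite directions there, from −0.41 to 0.88 in whole libraries. Prps2 and Msl3 were higher and Tmsb4x and Hccs lower in XX testes at both stages. The median therefore does not exclude a batch that moves single genes of the stretch. XY chromosomes as such would raise them in XY testes, but the highest class median of XY testes over XX ovaries was 0.167. A candidate explanation is an extra copy of this stretch of the X in the XY ovaries libraries. The whole-library medians lie near the 1 that a second copy would give. Class medians, however, went down to 0.59 against XX ovaries and 0.566 against XY testes. Single genes also lay apart from 1: against XX ovaries Tmsb4x was at 0.44 and Prps2 at 2.81 in whole libraries. Within classes that measured it, Prps2 ran from 0.63 (GABAergic or neurogenic progenitor-like) to 1.21 (unnamed cluster 3), and was at 6.25 in erythroid-like cells. The genes were chosen after being seen high. None of the 318 windows of 7 genes elsewhere on the X reached the 0.791 of the window that holds them against XX testes. The labels give XY- and XY-Sry as the genotypes and no reason for a difference at the X.

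The E16.5 XX testes library had 133 Y-linked UMIs (1.14 CPM), far from the other XX libraries, which had 2, 3 and 5. Free RNA or swapped barcodes would give them to cells with and without Xist alike, but among cells of at least 8000 UMIs 36.1% (30 of 83, exact Clopper-Pearson interval 25.9% to 47.4%, counting error only) of those without Xist had one, against 0.341% (25 of 7334) of those with Xist. XY cells in this library are a candidate explanation: of the 79 cells with a Y-linked UMI 40.5% (interval 29.6% to 52.1%) had Xist, against 80.8% of the others. In the other XX libraries 0 of 78, 71 and 37 such deep cells without Xist had a Y-linked UMI. Deep cells with Xist had one there at 0.0302%, 0.0361% and 0.0346%, below the 0.341% here. In the XY libraries 0.143% to 0.282% of cells with a Y-linked UMI had Xist. Those libraries held 0.160 to 0.350 CPM of Xist, against 1339 CPM in this one, so they had little free Xist RNA for cells to take up. The comparison therefore cannot show whether XY cells alone account for the 40.5%, and free Xist RNA and remaining doublets were not tested for. The 79 cells were spread over 13 of the 18 classes, and no biological source for XY cells in this library was tested.

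The other values lay apart from the rest of their group of 4 libraries by Dixon's test, which chance meets in about 1 of 20 groups; 132 groups were tested and 13 met it. The E18.5 XY testes library had the lowest Y-linked sum of the XY libraries, 119 CPM. The E18.5 XY ovaries library had 5.73% choroid plexus-like cells, the highest among the ovaries, the XY and the E18.5 libraries. The E16.5 XY ovaries library had 16.5% erythroid-like cells, the highest among the ovaries and the XY libraries. The E18.5 XX ovaries library had 1.06% erythroid-like cells, the lowest at E18.5, and 9.24% unipolar brush cell-like cells, the highest at E18.5. The E16.5 XY ovaries library had 11.9% granule progenitor-like cells, the lowest of the ovaries libraries, and 3.27% cells of unnamed cluster 2, the lowest of the XY libraries. The E18.5 XX testes library had 10.5% astroglia or radial glia-like cells, the lowest of the XX libraries.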

How the results depend on the processing

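Of 2075 values of 107 named genes under other settings, 1933 kept their direction and their side of the threshold, 142 kept the direction but missed the threshold (116 of them with 1 library left out), and 0 reversed; class and gene pairs by chromosomes ranged from 54 to 76 over all settings. No paired analysis was possible because every library has the same replicate number, 1, so a replicate block would have 1 level; the pairs in the text match libraries on their other factors. Leaving out 1 library left its combination of stage, chromosomes and gonads without a library. The gonads by chromosomes term and the sums over neural classes were chosen after seeing the data. For the settings below the cause was not tested, except that a left-out library leaves 3 residual degrees of freedom.

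With DESeq2 the whole-library counts were 2 by gonads, 10 by chromosomes, 1636 by stage and 6 for gonads by stage, and the stage count within classes was 4232. With no filter on low counts they were 7 by gonads within classes, 3 by chromosomes in whole libraries and 3440 by stage within classes. Library totals gave 280 by stage, and thinned totals 2 by chromosomes. With the factor alone the counts were 4 by chromosomes, 1159 by stage and 5308 by stage within classes. With the gonads by chromosomes term they were 3, 2183 and 11868, and 6 class shares by stage. The stricter cell filter gave 3 by chromosomes, 136 by stage and 4 class shares by stage. Sums over neural classes gave 5 by chromosomes and 1030 by stage, and neural cells as the denominator gave 8 class shares by stage. Keeping doublets gave 5 class shares by stage and 5 maturation contrasts in place of 3: it ended GABAergic or neurogenic progenitor-like by gonads and added unnamed cluster 3 by gonads, and astroglia-like and unipolar brush cell-like by chromosomes. The doubled resolution gave 6 class shares by stage and the exact permutation 0, since its smallest p is 0.125. Of 29 list calls 2 held with an estimated correlation, and fry called 4 lists. With the 100 highest and 100 lowest genes 0 maturation contrasts held.

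Leaving out each library in turn gave 0 to 3 class and gene pairs by gonads, 1 to 4 genes by chromosomes, 0 to 7 by stage, 365 to 1284 pairs by stage within classes and 1702 to 6794 genes for gonads by chromosomes. It gave 0 to 3 class shares by stage, 27 to 40 list calls and 2 to 7 maturation contrasts, the last on 3 pairs, for which the smallest p is 0.25.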

Other observations

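The tests of other splits for gonads and for the interactions with stage were chosen only after the results were seen; those for chromosomes and stage were chosen before.

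The oestrogen receptor Esr1 was low and unevenly spread over the classes. It averaged 9.92 ± 2.05 CPM (SD, n = 8) in unnamed cluster 2, of which 10.8% had a UMI (median 13256.5 UMIs per cell), 4.17 in unnamed cluster 3 (4.33%, median 11327) and 2.76 in granule progenitor-like cells (3.83%, median 15715), against 0.241 in granule neuron-like cells (0.277%, median 11676) as background. Foxj1, a regulator of motile cilia, averaged 287 CPM in choroid plexus-like cells (over 4 libraries, with 866 of the 1034 cells from E18.5 XY ovaries) and 23.9 in astroglia or radial glia-like cells (11.8% of cells), against 1.47 in granule neuron-like cells (1.58%). Gli1 averaged 23.0 CPM in astroglia or radial glia-like cells and 16.7 in granule progenitor-like cells. Mki67 was at 698 CPM in granule progenitor-like cells, and Hes5 at 672, Gpm6b at 1401, Aqp4 at 70.9 and Gfap at 7.04 CPM in astroglia or radial glia-like cells. Tmsb4x was at 28556 CPM in microglia or macrophage-like cells.

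Some genes changed with stage in many classes. Of the 1282 genes called in any class, 136 were called in at least 3, 57 higher in each, 67 lower in each and 12 in both directions. Wdr89 was called higher in 9 classes, and Rassf3 and Ppp1r14c in 6. Ebf2, a transcription factor of early neurons in the Purkinje lineage list, and Pvalb were called lower in 6, and Meis2, the cell cycle inhibitor Cdkn1c and Tenm4 in 5. Of the Purkinje markers, Pcp4 also fell in granule progenitor-like cells (−1.34) while it rose in Purkinje-like cells (1.01), and Foxp2 fell in GABAergic interneuron-like cells (−1.50), beside Purkinje-like shares of 11.9% at E16.5 and 1.40% at E18.5; free RNA of Purkinje cells was not tested for. These genes were chosen after their values were seen.

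Other splits of the 8 libraries into 4 and 4 gave higher gene counts than the real contrasts, mainly through the split into concordant and discordant libraries, which points to a structure of the samples. By gonads, with 0 genes and 0 class pairs, the count of splits says nothing, since 33 of 33 give as many by construction (highest other 7888 and 36137); for 6 lists chance could not be excluded (29 of 33, highest other 13). By chromosomes it could not be excluded for 7 lists (29 of 33, highest other 14). For 1 gene by chromosomes 2 of 33 splits gave as many (highest other 7823) and for 58 pairs 3 of 33 (highest other 35897); for Xist and the Y-linked genes themselves chance is excluded by their levels, which followed the label in 8 of 8 libraries. By stage only the real split gave 16 lists (1 of 33, highest other 15), and a margin of 1 list leaves chance open. With doublets kept 15 lists were called, with 1 library left out 12 to 18 and with an estimated correlation 0, and other splits were not run under these settings. For 6 genes by stage (2 of 33, highest other 4179) and 1856 pairs (2 of 33, highest other 12524) the count does not exclude chance. The other split as large was the one into concordant and discordant libraries, and the highest of the remaining 31 gave 0 genes and 28 pairs; setting that split aside after it was seen gives no test. Beside chromosomes the highest of these 31 gave 0 genes and 71 pairs, and beside gonads 0 and 77. For gonads by stage and chromosomes by stage, with 0 genes each, the count says nothing either, since 32 of 32 splits give as many (highest other 6820 for each).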
